A study of Mus musculus with 4 samples.

How the data were processed

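Expression was measured in total RNA of mouse CD4+ T cells on 4 Affymetrix mouse genome expression arrays, 1 array for each of 4 groups. The deposited values are log2 expression values per probe set, made by the authors with RMA (robust multi-array average, a background correction and summary of the probes of a probe set), per the submitters' processing notes. Those notes give no version, and they do not say whether the arrays were normalized together. The median of the 45037 probe sets outside the array's own controls was 5.77 in Th1 wild type, 6.01 in Th1 STAT4-deficient, 5.77 in Th2 wild type and 5.63 in Th2 STAT6-deficient cells, and the 75th percentile ran from 7.53 to 8.10. The 4 arrays as deposited therefore do not share 1 distribution, as joint quantile normalization would have given.

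The table held 45101 probe sets, of which 64 were controls. A platform annotation gave 1 gene for 34945 of the others, several for 932 and none for 9160. Only probe sets with 1 gene were used. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, which matched 34741 probe sets, and the annotation's symbol was kept for the rest. The table also gave the order of genes along each chromosome, used for the genes on each side of Stat4 and Stat6. No coordinates from it are given, since the deposited values name no genome build. The 18193 genes were each represented by the probe set with the highest mean over the 4 arrays, and 9010 of them had several probe sets. Folds and differences are those of this main probe set, and other probe sets of a gene can differ much less.

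The comparisons were Th1 STAT4-deficient minus Th1 wild type (STAT4 loss), Th2 STAT6-deficient minus Th2 wild type (STAT6 loss), Th1 wild type minus Th2 wild type, and Th1 STAT4-deficient minus Th2 STAT6-deficient. With 1 array per group there is no replicate spread, no test and no p-value, and every difference describes these arrays. A gene was called where its log2 values differed by at least 1 (2-fold) and the brighter array reached the pooled median of all probe sets, 5.82. "Higher" and "lower" refer to these calls unless a value is given. As a technical guide, the disagreement between probe sets of 1 gene in the same difference was measured; its SD (log2) was 0.48 for STAT4 loss, 0.65 for STAT6 loss, 0.71 between the wild types and 0.85 between the knockouts. It covers probe behaviour, not variation between mice or cultures. It was measured over changed and unchanged genes alike, so changed genes whose probe sets respond unequally add to it.

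Before the data were examined, 26 gene lists with 402 members were fixed; 361 members were measured. They cover Th1, Th2, Th17, regulatory, naive and memory T cells, cytotoxic genes, chemokines, interferon-stimulated genes, the JAK-STAT pathway and its feedback genes, the T cell receptor response, cell cycle, cholesterol synthesis, glycolysis, stress, cell death, histone and DNA methylation enzymes, reference genes, sex-linked genes, T lineage markers, and markers of B, myeloid, CD8 and NK, mast, neutrophil, erythroid and platelet cells. For each list the number of called members is given among those that reached the level minimum in the comparison, with the list's median difference. That median's percentile among 10000 random lists of the same size, matched on mean level in 10 bins, describes where the list stands among the genes of these arrays. A rule, also fixed before, set the genes to be named. Among them were the 12 with the largest fold in each direction (6 for the knockout comparison). The probe sets of these at the level minimum all had to differ the same way. Stat4 and Stat6, up to 4 called members per list with the largest difference, and all members of the Th1, Th2 and JAK-STAT lists were added. Not all genes that the rule gave are named below. Some named genes fall outside that rule and were chosen after their values were seen. These are Prdm1, Batf, Csf2, the genes listed as shared by both losses or near the targeted genes and the type I interferon genes other than Ifna2. They also include list members named beyond the 4, such as Gzmb, Gzmc, Ccr2, Irf7, Irf1, Irf4, Irf9, Psmb8, Psmb9, Rsad2, Ifit1, Nfkbiz, Cd3d, Kmt2b, Xist and Eif2s3y.

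For comparisons that share an array, 20 simulated sets of unchanged arrays gave a reference value, with probe-set disagreement as the only noise. Their noise was fitted per array to the probe-set disagreement of all pairs. That fit did not reproduce each pair, so a simulation with the noise of the 2 pairs as measured was added after the values were seen. In it 50% or 100% of the loss's noise variance lay in the shared array. Overlaps of called genes stand beside n1 × n2 / N, the overlap of independent lists. Shares carry 95% Wilson intervals, which cover the number of genes alone. The scripts were tested on simulated arrays. The changed genes were drawn from those at least 2 log2 units above the level minimum, so recovery of dimmer genes was not tested. In the simulation of STAT4 loss, 60.0% of 50 genes changed 2-fold and 100.0% of 50 changed 4-fold were called, as were 3.91% of 12138 unchanged genes. For STAT6 loss these were 56.0%, 92.0% and 13.0% of 11214 unchanged genes, since the noise is larger there.

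Alternatives fixed in advance were no level minimum or one at the 75th percentile (7.76), a fold of 1.5 or 3, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at (which can match several transcripts), centring each difference on its median over genes, and removing a loess curve (span 0.3) of the difference on the mean level. Quantile normalization of the 4 arrays and centring on the 18 bacterial hybridization controls were added after the arrays' distributions were seen to differ. Of the calls of list members 59 of 89 in STAT4 loss, 134 of 165 in STAT6 loss, 128 of 174 between the wild types and 74 of 109 between the knockouts were the same under all 4 scalings. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.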

Results

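The study asked how STAT4 and STAT6, the transcription factors that carry interleukin-12 and interleukin-4 signals, shape gene expression as helper T cells differentiate. Naive CD4+ T cells sorted from mouse spleen and lymph nodes were activated for 3 days through CD3 and CD28 and then kept for 4 days in interleukin-2. Th1 cultures received interleukin-12 and an antibody against interleukin-4, and Th2 cultures received interleukin-4 and an antibody against interferon gamma. On day 7 the cells were restimulated for 2 h through CD3 and CD28 with the same polarizing cytokine. One array each was made from Th1 wild type, Th1 STAT4-deficient, Th2 wild type and Th2 STAT6-deficient cells, so no difference below has a replicate check and the number of arrays limits every statement.

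Across probe sets the arrays correlated with r between 0.92 and 0.96, highest for the 2 Th1 arrays. RNA quality differed on the STAT6-deficient array. The beta-actin control signal at the 3′ end exceeded that at the 5′ end by 2.08 log2 units there, against 0.85 in Th2 wild type, 0.66 in Th1 STAT4-deficient and 0.32 in Th1 wild type cells. For the Gapdh control the same difference was 0.77, 0.00, 0.17 and −0.16. The median difference over all genes was 0.17 for STAT4 loss, −0.19 for STAT6 loss, −0.10 between the wild types and 0.21 between the knockouts; list medians below are given without subtracting it.

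The only Stat4 probe set used gave a signal 4.78-fold lower in Th1 STAT4-deficient than in Th1 wild type cells, at 9.20 against 11.45. It read 8.96 in Th2 wild type and 9.90 in Th2 STAT6-deficient cells. Stat6 did not separate the Th2 arrays by as much as 2-fold. The brighter of its probe sets read 10.92 in STAT6-deficient and 10.93 in wild type cells, and the dimmer one read 8.40 and 8.93. In the Th1 arrays these probe sets read 11.17 and 9.50 in wild type cells, and 11.67 and 9.90 in STAT4-deficient cells. Whether the probes lie in the deleted part of either gene is not known here, and a probe outside it checks nothing about the genotype.

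Without STAT4, Th1 cells had lower transcripts for several cytokines and for much of the Th1 list. Ifng, the signature Th1 cytokine, was 17.6-fold lower (10.54 against 14.67), Il21 198-fold lower and Il10 112-fold lower. Another Il21 probe set differed by only −2.49 log2 units. Il21 belongs to the Th17 list and Il10 to the Th2 list, and both were also bright in Th2 wild type cells (11.62 and 13.87). Of the 21 Th1 genes at the level minimum, 15 were lower and none higher, with a median of −1.31 (percentile 0 of random lists); other scalings gave from 10 (hybridization controls) to 18 lower (median centring). Il12rb2, the interleukin-12 receptor chain that activates STAT4, was lower by 3.10 log2 units. Cxcr6 (−2.99), Cxcr3 (−2.59), Hlx (−2.26) and the interleukin-18 receptor genes Il18rap (−2.23) and Il18r1 (−1.85) were lower as well, as log2 differences. Tbx21, which encodes the Th1 regulator T-bet, differed by −0.91, under the 2-fold limit, as did Tnf (−0.90), Lta (−0.66), Fasl (−0.85) and Eomes (−0.54). Tbx21 passed the limit after median centring (−1.08) and not after quantile normalization (−0.57). Runx3 differed by −1.15 on its main probe set but by 0.11 on another.

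Cytotoxic genes were lower together, 9 of 13 with none higher and a median of −1.77 (percentile 0). Among them Klrk1, which encodes the activating receptor NKG2D, was 29.7-fold lower, granzyme A (Gzma) was 16.5-fold lower, and Klrc1 (−4.11), Nkg7 (−3.37) and granzyme B (Gzmb, −1.13) were lower too. The Gzmb call held under only 1 of the 4 other scalings. Of the chemokine and receptor genes 8 of 18 were lower and 2 higher, with a median of −0.56 (percentile 0.01); centred on the hybridization controls these were 7, 4 and −0.18. Ccr1 (−3.01), Ccl5 (−2.46), Ccl3 (−2.14), Xcl1 (−2.05) and Ccr2 (−2.02) were lower, while Ccr8 and Ccl1 were 2.56 and 2.41 higher. This list overlaps the Th1 and Th2 lists, and of its called members only Ccr1 and Ccr2 belong to neither. Plac8 (33.2-fold), Gja1 (84.8-fold), Esm1 (53.5-fold), Serpinb1a (32.1-fold), Mmp13 (24.4-fold), Ffar2 (20.1-fold), Gem (18.4-fold) and the unnamed transcript G530011O06Rik (18.9-fold) completed the 12 genes furthest below wild type. The Gja1 probe sets ran from −6.41 to −2.50 log2 units.

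Part of the Th2 program stood higher in Th1 cells without STAT4. Il4 was 8.03-fold and Il13 7.21-fold higher, and Gata3, the Th2 master regulator, was 2.52 log2 units higher. Il5 did not reach the level minimum in either Th1 array (4.99 and 4.34). The Th2 list as a whole was split, with 5 of 19 members higher and 5 lower. Its lower members were Il10, Il24 (−2.26), Maf (−1.58, with 1 probe set at 0.40), Ecm1 (−1.53) and Nfil3 (−1.38). Its median was −0.26 (percentile 8.09) and turned to 0.29 when arrays were centred on the hybridization controls. Foxp3, the regulatory T cell factor, was 2.47 log2 units higher, at 6.81 against 4.34, beside 1.74 for Itgae; 2 of 11 regulatory T genes were higher and 1, Ctla4, was lower (−2.65). The genes furthest above wild type were Lad1 (24.0-fold), Pdlim4 (22.9-fold), Ccn3 (17.6-fold), Alox5ap, which encodes the 5-lipoxygenase activating protein (17.3-fold), Mcoln2 (10.9-fold), Trgv4 (10.9-fold), Osbpl3 (10.2-fold), Gpr34 (8.90-fold), Myo6 (8.82-fold) and Atp1b1 (8.78-fold).

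Parts of the T cell receptor response and stress lists were lower in the STAT4-deficient Th1 array as well. Of 23 T cell receptor response genes 10 were lower and none higher (median −0.66, percentile 0.03). The largest differences were in Nr4a2 (−3.14, with another probe set at −0.32), Fos (−1.85), Jun (−1.83) and Egr1 (−1.76). Il2 (−0.14), Cd69 (−0.19) and Irf4 (−0.28) were close to wild type. The list's median shrank to −0.29 after loess (8 lower) and to −0.28 both after quantile normalization (7 lower) and with arrays centred on the hybridization controls (8 lower). Stress response genes were lower in 7 of 15 (median −0.70), led by Atf3 (−2.06), Hspa1a (−1.88) and Hspa1b (−1.61); centred on the hybridization controls 3 were lower (median −0.31). Glycolysis and hypoxia genes were lower in 5 of 19 (median −0.62, percentile 0.11), with Egln3 at −3.31, the glucose transporter gene Slc2a1 at −2.13 and hexokinase 2 (Hk2) at −1.75. When arrays were centred on the hybridization controls, 3 of this last list were higher and 4 lower. The STAT feedback genes Socs3 (−2.75), Bcl3 (−1.57) and Bcl6 (−1.14) were the lower ones among 11 (median −0.61, percentile 0.81), and the median was −0.23 after quantile normalization and −0.22 with the hybridization controls. Interferon-stimulated genes had 4 higher and 2 lower of 26, with a median of 0.35 (percentile 99.99). Irgm1 (1.86), Iigp1 (1.33), Irf1 (1.26) and Rsad2 (1.17) were higher, and Gbp2 (−1.5) and Gbp3 (−1.35) lower; with arrays centred on the hybridization controls 9 were higher and 1 lower. The 3′ minus 5′ difference of the actin control was 0.34 log2 units larger in this array than in its wild type.

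In all, 1452 of 12608 genes at the level minimum were called in STAT4 loss, 779 higher and 673 lower. The share that was higher, 53.7%, depended on the scaling: it was 33.8% after centring on the median gene, 42.1% after loess, 46.4% after quantile normalization and 87.4% after centring on the hybridization controls. With a level minimum at the 75th percentile it was 40.7%. Of 604 called genes with several probe sets, 79.5% had all of them on the same side.

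**Figure D1:**
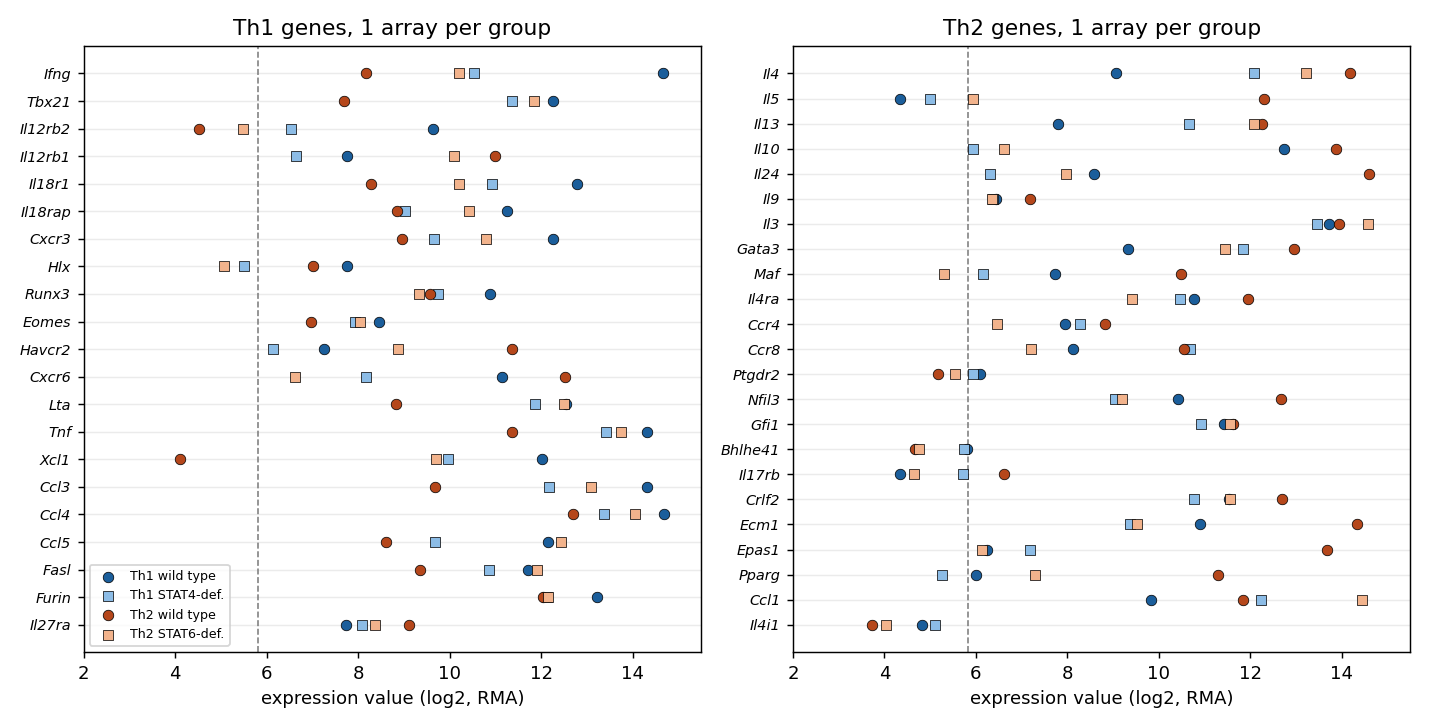
Expression values (log2, RMA) of the measured Th1 genes (left) and Th2 genes (right) on the 4 arrays, 1 point per array, with the level minimum of 5.82 as a dashed line. Ifng lay at 14.67 in Th1 wild type and between 8.18 and 10.54 on the other arrays, and Il5 at 12.31 in Th2 wild type and between 4.34 and 5.95 on the others.

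Without STAT6, Th2 cells had lower signal for most Th2 genes and higher signal for many Th1 genes. Of 20 Th2 genes at the level minimum 14 were lower and 1, Ccl1, was higher (2.62); the median was −2.45 (percentile 0). Epas1, which encodes the hypoxia-inducible factor HIF-2α, was 185-fold lower, Il10 154-fold lower and Il24 99.0-fold lower. Il5 was lower by 6.36 log2 units, and Ecm1 (−4.81), Pparg (−4.01), Nfil3 (−3.49), Ccr8 (−3.35), Il4ra (−2.53) and Ccr4 (−2.37) were lower too. Gata3 read 11.45 against 12.95 in wild type. Maf differed by −5.16 on its main probe set, with 1 probe set at 0.05. The cytokine genes Il4 (−0.95) and Il13 (−0.18) were under the 2-fold limit, at 13.22 and 12.08 without STAT6. Prdm1, which encodes the transcription factor Blimp-1, and Batf were also lower (−5.48 and −2.70).

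Of 20 Th1 genes at the level minimum 13 were higher in the STAT6-deficient array and 3 lower, with a median of 1.71 (percentile 100). Xcl1 was 48.9-fold higher, Tbx21 was higher by 4.16 log2 units, Ccl5 by 3.82, Lta by 3.68, Ccl3 by 3.42, Fasl by 2.55, Tnf by 2.39 and Ifng by 2.02. Ifng stood at 10.20, below the 14.67 of Th1 wild type cells. The 3 lower members were Cxcr6 (−5.90), Havcr2 (−2.49) and Hlx (−1.93). Chemokine and receptor genes, a list that shares members with the Th1 and Th2 lists, went both ways, 9 higher and 6 lower of 17. Cxcl10 was 33.1-fold higher and Ccr1 lower (−5.16).

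The list with the largest median difference was that of interferon-stimulated genes, with 22 of 27 higher, none lower and a median of 2.94 (percentile 100). Oasl2 was 148-fold higher, Ifit3 89.5-fold, Ifit2 43.9-fold, and Oas2, Ifit1, Iigp1 and Rsad2 were 4.64, 4.57, 4.53 and 4.48 log2 units higher. Irf7, a regulator of type I interferon genes, was 2.53 higher, while Psmb8 (−0.10), Psmb9 (0.11) and Irf9 (0.15) were near wild type. Ifna2, an interferon alpha gene, was itself 55.1-fold higher, at 10.87 against 5.09. Other genes furthest above wild type were Idi2 (53.5-fold), Ipcef1 (46.4-fold), the costimulatory ligand gene Cd70 (37.1-fold), 2900026A02Rik (36.0-fold), Acsl6 (35.5-fold) and Dapl1 (32.5-fold). Other probe sets of 2900026A02Rik and Acsl6 differed by 1.03 and 2.30 log2 units. The actin 3′ minus 5′ difference of 2.08 belongs to the same array as these values.

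Genes of proliferation and metabolism were lower without STAT6, on the array whose actin 3′ minus 5′ difference was 1.23 log2 units larger than in wild type. Of 23 cell cycle genes 18 were lower and none higher (median −1.24, percentile 0), among them Rrm2 (−2.50), Aurkb (−2.11), Aurka (−1.98) and Ccnb2 (−1.65). Glycolysis and hypoxia genes were lower in 10 of 19 (median −1.0, percentile 0.03), led by Bnip3 (−4.38), and cholesterol synthesis genes in 8 of 16 (median −1.04, percentile 0.10), led by Hsd17b7 (−2.35), Dhcr7 (−2.26) and Lss (−2.22). Myeloid and dendritic cell markers were lower on the same array, 3 of 6 (median −1.16, percentile 1.88). Stress response genes were lower in 9 of 15 (median −1.17), including Ddit4 (−2.66) and Xbp1 (−2.16). After quantile normalization 15 cell cycle, 9 glycolysis and hypoxia, 6 cholesterol synthesis and 4 stress response genes were lower. The medians of these 4 lists stayed below −0.7. The lower myeloid and dendritic cell markers, Adgre1, Itgax and Fcgr3, kept their calls under all 4 other scalings. Regulatory T genes were lower in 5 of 10 and higher in 1 (median −1.05, percentile 0.23), with Ctla4 at −3.27 and Ikzf2 at 2.10; after quantile normalization 2 were lower. T cell receptor response genes had 7 higher and 2 lower of 23 (median 0.29, percentile 98.9); Il2 was 2.31 and Cd69 2.04 higher. STAT feedback genes were lower in 4 of 11, led by Socs3 (−2.61) and Socs1 (−2.12), and Bcl6 differed by 1.70 on its main probe set and −0.45 on another. Of the JAK-STAT genes Jak3 (−1.78), Stat3 (−1.20, with another probe set at 0.79) and Jak1 (−1.10) were lower among 10; after median centring, loess or quantile normalization Jak1 was not called.

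The genes furthest below wild type were the matrix metalloproteinase gene Mmp10 (241-fold), Cyp11a1, which encodes the first enzyme of steroid hormone synthesis (206-fold), Cxcl3 (160-fold), Rnf152 (157-fold), Gzma (156-fold), Il6 (148-fold), Adamtsl3 (120-fold), Tanc2 (117-fold) and Emilin2 (96.9-fold), besides Epas1, Il10 and Il24. Another Cyp11a1 probe set differed by only −1.93 log2 units. In all 3043 of 11490 genes at the level minimum were called, 806 higher and 2237 lower. The share that was higher, 26.5%, became 38.8% after centring on the median gene, 41.2% after loess, 43.5% after quantile normalization and 20.1% after centring on the hybridization controls. Of 1328 called genes with several probe sets, 83.9% had all of them on the same side. Among unchanged genes simulated with this pair's probe-set disagreement 13.0% were called, so calls near the 2-fold limit are not secure. Simulated unchanged arrays gave 1452 higher and 1305 lower with noise fitted per array, more higher than the 806 observed. With the noise of the pairs as measured they gave 1640 calls in all. These simulated arrays hold no shift between arrays.

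**Figure D2:**
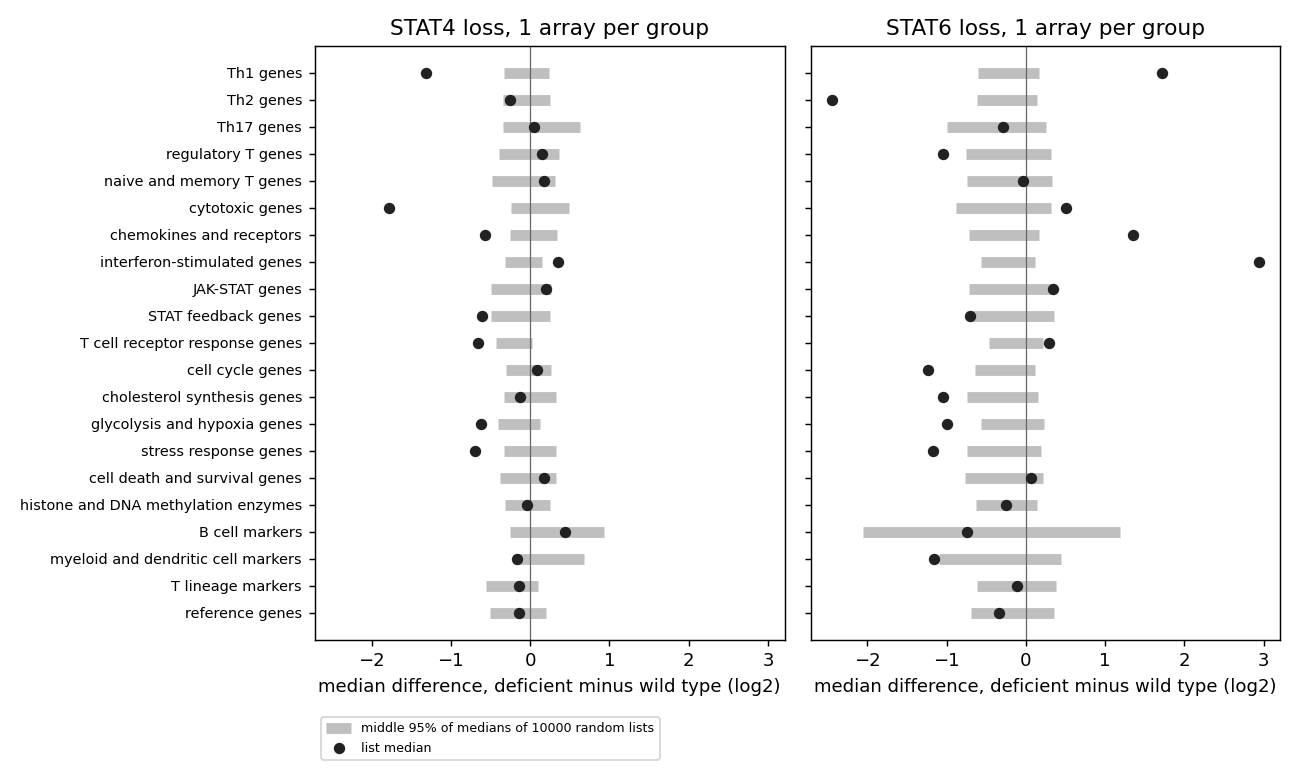
Median log2 difference (deficient minus wild type) of each fixed list with at least 3 members at the level minimum, for STAT4 loss (left) and STAT6 loss (right), with the middle 95% of the medians of 10000 level-matched random lists as grey bars. Th1 genes lay at −1.31 and 1.71 and interferon-stimulated genes at 0.35 and 2.94.

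Wild type Th1 and Th2 cells were compared to define the polarized genes, those that differ between the culture conditions. The sample titles name these controls STAT4-wild type and STAT6-wild type. Whether they came from the same mice or were processed together is not given. Differences of source or processing therefore cannot be told apart from those of culture condition. Th1 cells had higher signal for Klrd1, which encodes the receptor chain CD94 (254-fold), Xcl1 (243-fold), Ifng (90.0-fold), Serpinb1a (65.3-fold), the costimulatory ligand gene Cd86 (49.2-fold), Klrk1 (47.3-fold), Plac8 (37.7-fold), Nkg7 (37.1-fold), Il12rb2 (34.5-fold), 4933430I17Rik (25.7-fold), Ccl3 (24.9-fold) and Serpinb5 (24.3-fold). Th2 cells had higher signal for Il6 (323-fold), Cyp11a1 (299-fold), Rnf152 (293-fold), Il5 (250-fold), Cxcl3 (179-fold), Epas1 (173-fold), Arfgef3 (103-fold), Mmp10 (98.6-fold), Adamtsl3 (73.7-fold), Il24 (65.0-fold), Serpinf1 (57.1-fold) and Sval1 (53.7-fold). Other probe sets of Cyp11a1 and Serpinf1 differed by only −1.04 and −1.84 log2 units. Of 21 Th1 genes 16 were higher in Th1 cells and 4 higher in Th2 cells (median 2.42, percentile 100). Those 4 were Havcr2 (−4.12), Il12rb1 (−3.22), Il27ra (−1.38) and Cxcr6 (−1.37). Of 21 Th2 genes 16 were higher in Th2 cells and none in Th1 cells (median −2.28, percentile 0), including Il4 (−5.11), Il13 (−4.45) and Gata3 (−3.64).

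Other programs separated the wild types too. Cell cycle genes stood higher in Th2 cells, 21 of 23, with a median of −2.20 (percentile 0), and glycolysis and hypoxia genes in 12 of 19 (median −1.39, percentile 0). Bnip3 differed by −4.56, Aldoc by −3.36, Tyms by −3.44 and Rrm2 by −3.21. Regulatory T genes were higher in Th2 cells in 8 of 10 (median −1.29), and in 4 after quantile normalization. T cell receptor response genes were higher in Th1 cells in 14 of 23 and lower in 1, Tnfrsf9 (median 1.29, percentile 100), with Jun at 2.72, Fosb at 2.18 and Il2 at 2.07; 9 were higher with the hybridization controls. Cytotoxic genes were higher in Th1 cells in 7 of 13, but Gzmb (−1.95), Gzmc (−1.27) and Gzma (−1.08) were higher in Th2 cells. Of 12111 genes 986 were higher in Th1 and 3072 in Th2 cells. Simulated unchanged arrays gave 863 and 845 with noise fitted per array, and 991 and 1180 with the noise of the pairs as measured (50% of the STAT4-loss variance in the Th1 array). As deposited, the number higher in Th1 is thus no larger than the second of these simulations gave. Its noise includes changed genes whose probe sets respond unequally, such as Cyp11a1, so it may be overstated. Single genes near the limit are not secure. That number was 1148 after median centring, 1314 after loess, 1409 after quantile normalization and 468 with the hybridization controls. The simulated arrays hold no shift between arrays, so they do not settle how many of these genes differ. The 24.3% that were higher in Th1 became 41.5% after loess, 45.2% after quantile normalization and 8.90% after centring on the hybridization controls.

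Between the 2 knockouts, the Th1 and Th2 lists lay close to the random lists. The Th1 list had 2 members higher in the Th1 STAT4-deficient and 6 higher in the Th2 STAT6-deficient array of 20 (median −0.42, percentile 13.9), and the Th2 list 4 and 6 of 20 (median −0.39, percentile 8.79). Ifng differed by 0.33 and Gata3 by 0.39, and Tbx21 by −0.50. Il4 (−1.15) and Il13 (−1.42) stayed higher in the Th2 array. Interferon-stimulated genes were higher in the STAT6-deficient array in 19 of 27 (median −2.64, percentile 0), Mx1, Usp18 and Oasl2 among them. Over all genes, Cmpk2 (199-fold), Mx1 (164-fold), Usp18 (62.7-fold), Oasl2 (51.0-fold), Idi2 (42.7-fold) and Trim30d (37.1-fold) stood furthest higher in that array. Other probe sets of Cmpk2 and Trim30d differed by only −1.78 and −2.06 log2 units. Myl10 (20.3-fold), Klrb1f (13.4-fold), Cnr2 (12.8-fold), Ccr8 (11.2-fold), Tet3 (7.81-fold) and Ltc4s (7.30-fold) were higher in the STAT4-deficient array. Cell cycle genes were higher in the STAT6-deficient array in 10 of 23 (median −0.98), and in 6 after quantile normalization. Of 12582 genes 1585 were higher and 1290 lower in the STAT4-deficient array, where simulated unchanged arrays gave 1312 and 1458. The share higher, 55.1%, was 34.3% after median centring and 68.0% after centring on the hybridization controls. With a level minimum at the 75th percentile it was 26.4% (366 higher and 1020 lower), so the excess of higher genes rests on dim ones. Of 1020 called genes with several probe sets 65.3% had them all on 1 side.

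STAT4 loss and STAT6 loss share no array. Across the 10951 genes at the level minimum in both, their log2 differences correlated with Pearson r = 0.21 and Spearman rho = 0.15; genes are not independent replicates. Il10, Il21, Mmp13, Gzma, Gja1, Esm1, Ccr1 and Cxcr6 were among 270 genes lower in both, where independent lists would share 115. That ratio of 2.34 was 1.42 at a fold of 1.5 (723 against 508) and 5.53 at a fold of 3 (89 against 16.1). Lad1, Ccn3, Alox5ap, Rtp4, Ccl1, Tox and Osbpl3 were among 121 higher in both, where independent lists would share 39.0. Ifng, Xcl1, Ccl5 and Cxcr3 were among 65 genes lower without STAT4 and higher without STAT6, against 41.8 for independent lists, and Gata3 and Ccr8 among 75 with the opposite pattern, against 108. The actin 3′ minus 5′ difference was larger in both knockouts than in their wild types, by 0.34 and 1.23 log2 units.

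**Figure D3:**
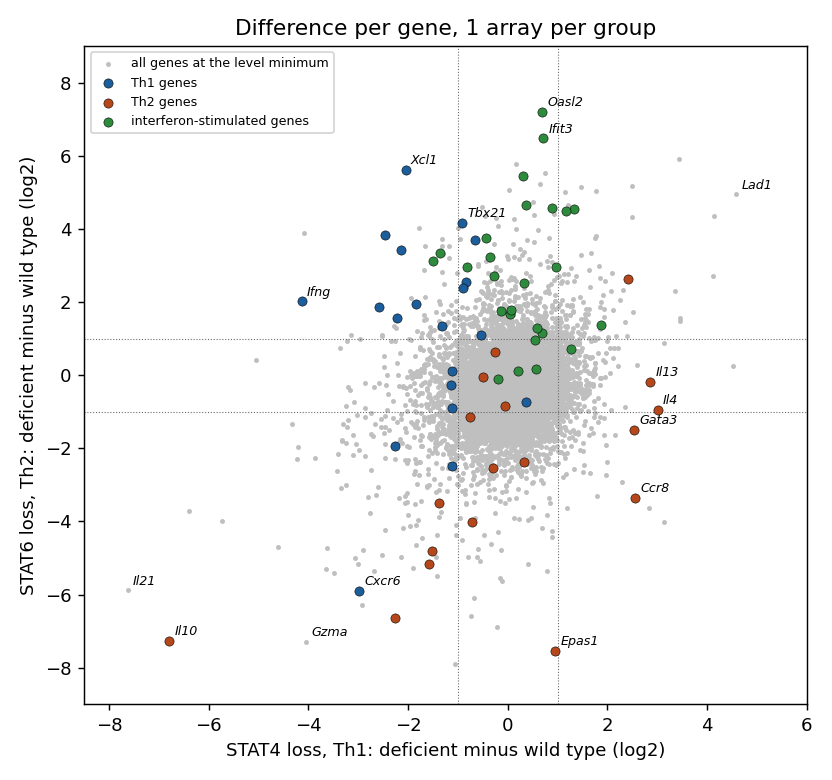
Log2 difference of each gene for STAT4 loss (horizontal) and STAT6 loss (vertical), with Th1, Th2 and interferon-stimulated genes coloured and dotted lines at 1 and −1. Ifng and Xcl1 lie at the upper left, Il10 and Il21 at the lower left, and Oasl2 and Ifit3 at the top near no STAT4 difference.

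Of the 986 genes higher in Th1 than Th2 wild type cells, 203 (20.6%, 95% interval 18.2 to 23.2) were lower without STAT4, Ifng, Klrk1, Nkg7 and Plac8 among them, against 5.05% of level-matched genes. Both comparisons use the Th1 wild type array, and simulated unchanged arrays gave 31.2% with noise fitted per array. That fit overstates the noise of STAT4 loss, with 863 genes higher and 866.5 lower against 779 and 673 observed. With the noise of the pairs as measured, the share was 7.32% or 17.8%, as 50% or 100% of the STAT4-loss noise variance lay in the shared array. How much of the 20.6% comes from the shared array therefore depends on the noise assumed. The correlation of STAT4 loss with the wild type difference was −0.31 (simulated −0.55, or −0.36 and −0.70 by pair). The covariance was −0.224 (simulated −0.249, or −0.131 and −0.254 by pair). Of the 3072 genes higher in Th2 cells, 1366 (44.5%, interval 42.7 to 46.2) were lower without STAT6, Il5, Epas1, Il6 and Cyp11a1 among them, against 20.7% of level-matched genes and 31.5% with simulated unchanged arrays (23.7% and 60.9% by pair). The correlation was 0.60 (simulated 0.43, or 0.48 and 0.91 by pair) and the covariance 0.658 (simulated 0.230, or 0.233 and 0.451 by pair). Independent lists would have shared 56.8 genes on the Th1 side and 609 on the Th2 side. Part or all of each excess may come from the shared array, since simulated shares lay on both sides of the observed ones. On the Th2 side the covariance, however, lay above every simulated value.

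Genes from arrays that the loss does not use gave smaller shares; these genes differ by genotype within 1 culture condition, so they are not the polarized genes. Among genes at the level minimum in both losses, 726 were higher without STAT6 in Th2 cells, and 65 of them (8.95%, interval 7.09 to 11.3) were lower without STAT4, against 5.93% of level-matched genes, while 121 (16.7%) were higher. Likewise 589 were higher without STAT4 in Th1 cells, and 75 of them (12.7%, interval 10.3 to 15.7) were lower without STAT6, against 20.9%, while 121 (20.5%) were higher. The wild type and knockout Th1 against Th2 differences, which share no array, correlated with r = 0.39 over 11546 genes; 284 genes were higher on the Th1 side in both, where independent lists would share 85.0, and 611 on the Th2 side, against 301.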

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

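The tests on the interferon-stimulated genes, on restimulation and on 5′ signal were chosen only after the patterns they concern had been seen; the tests of array scaling for the genes lower in both knockouts, and of the chromosome around the targeted genes, were set before their values were computed. The windows of 25 and 100 genes and the share without the receptor genes were added after the first window had been seen.

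In 17 genes of the fixed lists, STAT4 loss and STAT6 loss moved the signal at least 2-fold in opposite directions, and 12 of them did so under all 4 other scalings as well; Ccl4, S1pr1, Gbp3, Bcl6 and Nr4a2 did not. The difference between the losses was not tested, since each rests on 1 array per group and a different STAT was missing. Ifng (log2 −4.139 without STAT4 and 2.019 without STAT6), Il18r1 (−1.849 and 1.937), Il18rap (−2.228 and 1.57), Cxcr3 (−2.591 and 1.855), Xcl1 (−2.052 and 5.612), Ccl3 (−2.138 and 3.417), Ccl4 (−1.311 and 1.355) and Ccl5 (−2.464 and 3.825) belong to the Th1 list. Gata3 (2.524 and −1.499) and Ccr8 (2.56 and −3.348) belong to the Th2 list, and S1pr1 (1.375 and −1.156) moved like them. The receptor gene Klrd1 (−1.774 and 4.016), Bcl6 (−1.136 and 1.699, with another probe set at −0.45 without STAT6), the guanylate-binding protein genes Gbp2 (−1.5 and 3.13) and Gbp3 (−1.353 and 3.335) and the activation genes Nr4a2 (−3.143 and 1.092) and Nfkbiz (−1.718 and 1.143) moved like the Th1 genes. The beta-actin control, which no comparison uses, had a 3′ minus 5′ difference of 2.084 log2 units in the Th2 STAT6-deficient array, above the 0.85 of its wild type.

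Interferon-stimulated genes stood far above wild type in the STAT6-deficient array. Array scaling is argued against, since the list's median was 3.17 after quantile normalization of the arrays. The list's median did not follow the Ifng transcript level. That median lay 2.70 log2 units higher in this array than in Th1 wild type cells, where Ifng was far higher. Members were split, however. Oasl2 (11.59 against 5.24) and Ifit3 (12.98 against 8.48) stood far above Th1 wild type. Gbp2 (13.05 against 13.42) and Gbp3 (11.46 against 11.35) were close to it. The antibody against interferon gamma was also in the Th2 cultures. A response to interferon gamma is not excluded, because Th1 wild type and Th2 STAT6-deficient cells may respond to it unequally, which was not measured. Of 8 measured type I interferon genes 6 were called higher and none lower without STAT6, including Ifnb1 (14.4-fold), Ifna2 (55.1-fold), Ifna4 (19.7-fold) and Ifna5 (6.18-fold), so type I interferon made in that culture is a candidate explanation, though probe sets of this family may cross-hybridize. What would have raised it, the missing STAT6 or an event in 1 culture, cannot be separated with 1 array.

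The genes lower in both knockouts, Il10, Il21, Gzma and Ccr1 among them, exceeded the number that independent lists would share. Quantile normalization left 234 shared genes, 3.05 times the independent number, which argues against scaling as the whole cause. Weaker 5′ signal in both knockout arrays stays open: relative to 3′ signal it fell by 0.34 (actin) and 0.33 (Gapdh) without STAT4 and by 1.23 and 0.77 without STAT6, and probe positions within the genes are not known. For the STAT6-deficient culture the T cell receptor response list gave no sign of restimulation weaker than in Th2 wild type cells. There the list had a median of 0.29, with 16 genes above wild type and 7 below. Th2 wild type cells themselves lay below Th1 wild type on this list (median 1.29). The list thus may not separate restimulation from helper program, so weaker restimulation is not excluded and full restimulation is not shown. Weaker restimulation may contribute in the STAT4-deficient culture. There the list's median was −0.66 and stayed below the random lists after quantile normalization (−0.28) and loess (−0.29). Loss of a STAT in each culture, the difference the design names, stays open and was not tested apart from other differences between the cultures.

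Knockout mice made in stem cells of another strain can keep that strain's chromosome around the targeted gene, and its sequence differences may alter probe signals. Around Stat6, 18 of the 68 genes at the level minimum among 50 on each side were called, the 52.5th percentile of windows of that size, which argues against a visible excess there. Around Stat4 the count was 17 of 67 (25.4%), the 99.0th percentile, and without the neighbouring receptor genes Il1r2, Il18r1 and Il18rap the share was 21.9% against a bound of 22.4%. With 25 genes on each side, none of them from that receptor cluster, it was 22.9% (percentile 93.5), and with 100 it was 19.4% (percentile 97.45), both under the bound set. The shares stayed above the 10.9% to 11.1% of the median window but passed the bound only at 50 genes, so another strain's chromosome around Stat4 stays open.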

How the results depend on the processing

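Quantile normalization and centring on the hybridization controls were chosen only after the arrays had been seen to differ. No paired analysis was possible because each group holds 1 array, and for the same reason leaving out replicates was not possible; STAT6 loss and the comparison of the knockouts rest on the STAT6-deficient array, whose 5′ signal was weak, and have no value without it. The cause of the changes below was not tested, except that a lower or higher limit on fold or level by construction takes in more or fewer genes.

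At a fold of 1.5, calls numbered 4010 (STAT4 loss), 5594 (STAT6 loss), 6877 (wild types) and 5954 (knockouts), and the shares of polarized genes lower without their STAT were 26.9% (Th1 side) and 55.4% (Th2 side). At a fold of 3 these were 408, 1279, 1709, 913, 16.4% and 37.8%. With a level minimum at the 75th percentile, STAT4 loss had 847 calls, the knockouts 1386, the Th1-side share was 32.3% and the correlation of the losses 0.26; with no minimum the share was 14.8% and the correlation 0.18. The correlation was 0.25 after loess and 0.25 after quantile normalization. Median centring gave shares of 23.7% and 38.7%, and averaging probe sets 47.2% on the Th2 side. Centring on the hybridization controls gave 2697 calls in STAT4 loss, a Th2-side share of 39.9%, and STAT4-loss medians of 0.29 for Th2 genes and 0.73 for interferon-stimulated genes. For single genes, Sc5d in STAT4 loss turned to 0.11 with averaged probe sets, and Kdm6b in STAT6 loss to −1.47 without _x_at and _s_at probe sets. The Th1 list stayed below −0.9 in STAT4 loss and above 1.5 in STAT6 loss under all 4 other scalings. Of the values recomputed for named genes 2938 moved by less than the disagreement between probe sets, 76 moved by more without turning, and 2 turned; of list medians 433 stayed within their bootstrap SD and 86 did not.

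Folds against an array under the level minimum, such as those of Il5, Xcl1 or Cxcl3, rest on signal near background on that side.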

Other observations

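The tests of type I against interferon gamma responses given here were chosen only after the interferon pattern had been seen.

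Cells without STAT6 also differed in genes outside the helper programs. Ezh2 (−1.74) and Suz12 (−1.03), which belong to the Polycomb complex that methylates histone H3, were lower. The maintenance DNA methyltransferase gene Dnmt1 (−1.29) and the DNA demethylase gene Tet3 (−2.62) were lower too. Dnmt3a (1.65), Kmt2b (1.25) and Kdm6b (1.88, with another probe set at −1.47) were higher. Of 23 histone and DNA methylation enzymes 3 were higher and 6 lower (median −0.25, percentile 49.5). After median centring, loess or quantile normalization 4 were higher and 4 lower, and Suz12 was not called. Without STAT4, Dnmt3a (1.15), Ezh1 (1.13) and Dnmt3b (1.10) were higher and Kdm5a lower (−1.30, with 1 probe set at 0.55), of 22 (median −0.04); after median centring none was higher and 3 were lower. Naive and memory T genes had 1 higher and 2 lower of 11 in STAT4 loss (median 0.18) and 3 higher and 4 lower of 11 in STAT6 loss (median −0.04). The latter became 3 higher and 2 lower after median centring (median 0.15), loess (0.18) and quantile normalization (0.19), with S1pr1 and Cd44 no longer called. The interleukin-7 receptor gene Il7r (−1.12 and −2.13) and the chromatin organizer gene Satb1 (−1.07 and −2.03) were lower in both. In STAT4 loss no member of that list was lower after loess, quantile normalization or centring on the hybridization controls. S1pr1, which guides exit from lymph nodes, was 1.38 higher without STAT4 and lower without STAT6 (−1.16). Cell death and survival genes had 2 higher and 2 lower of 13 in STAT4 loss (Bid 2.10 and Tnfsf10 2.06 against Pmaip1 −2.54 and Cdkn1a −1.37), and 2 higher and 1 lower of 13 in STAT6 loss (Bcl2l11 1.89 and Fas 1.61 against Pmaip1 −1.19). The latter became 3 higher and none lower after median centring, loess and quantile normalization.

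Th17 genes had 1 higher and 1 lower of 7 in STAT4 loss (Il6ra 1.48 and Il21) and 2 higher and 2 lower of 8 in STAT6 loss (Rora 3.72 and Ccl20 3.12 against Il21 and Il1r1, −3.40). Csf2, which encodes the growth factor GM-CSF, was lower without STAT4 (−2.52) and higher without STAT6 (1.06). Cell cycle genes in STAT4 loss had 1 of 22 lower (Rrm2, −1.09), with a median of 0.09 that was −0.08 after median centring. Centred on the hybridization controls 3 were higher and none lower (median 0.47). Cholesterol synthesis genes had 1 of 16 lower there (median −0.13, 0.25 with hybridization controls). In STAT6 loss cytotoxic genes had 3 higher and 3 lower of 9, among them Klrd1 (4.02) and Gzma. JAK-STAT genes in STAT4 loss had Stat4 lower and no other call among 10.

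T lineage markers were expressed on all arrays, with Cd3d between 13.22 and 13.73. Between the wild types 3 of 11 were higher in Th1 cells (Cd5 1.31, Cd3e 1.14 and Cd4 1.05), but none when arrays were centred on the hybridization controls. Between the knockouts 2 were higher in the STAT4-deficient array (Cd4 1.97 and Cd247 1.28) and 1 lower (Cd3g, −1.12). Of the same 11 only Cd28 was called in STAT4 loss (−1.01) and only Cd247 in STAT6 loss (−1.58), and the medians of −0.15 and −0.11 turned positive under some scalings. Of 10 reference genes none was called in STAT4 loss (median −0.14) and Actb was in STAT6 loss (median −0.34), at −1.52 on its main probe set and 0.47 on another. The female transcript Xist lay between 12.44 and 13.71 on the 4 arrays, and the Y-linked Eif2s3y between 2.73 and 3.63. Markers of other cells were mostly near or below the level minimum. In Th2 wild type cells, however, Cpa3 read 8.64, Cd8b1 8.54 and Adgre1 8.26. B cell markers had none called of 5 in STAT4 loss (median 0.44) and 1 of 3 higher in STAT6 loss (Cd22, 6.52 against 5.48). Myeloid and dendritic cell markers had 1 lower of 6 (Cd68, −1.50) and 3 lower of 6 (Adgre1 −2.33, Itgax −1.73 and Fcgr3 −1.59), with medians of −0.16 (percentile 3.94) and −1.16 (percentile 1.88). Of mast cell and basophil markers Cpa3 was lower in both (−1.33 and −3.74), 1 of 3 and 1 of 2 at the level minimum. Of CD8 and NK markers Cd8b1 was lower without STAT6 (−2.07), 1 of 2, and of erythroid and platelet markers Gp9 was (−1.08), its only member at the level minimum. The calls of Cd28 and Cpa3 in STAT4 loss and of Cd22 and Gp9 in STAT6 loss were each lost under at least 1 other scaling. Neutrophil, CD8 and NK, and erythroid and platelet markers and sex-linked genes had no call in STAT4 loss, nor did neutrophil markers and sex-linked genes in STAT6 loss.

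Genes listed as responding mainly to type I interferon, many of them also in the interferon-stimulated list, had a median of 4.34 in STAT6 loss (15 genes, percentile 100), and genes listed for interferon gamma one of 0.84 (12 genes, percentile 99.99). In STAT4 loss the medians were 0.51 (percentile 99.3) and 0.33 (percentile 97.9), with 13 genes each.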
